A study of Homo sapiens with 8 samples.

How the data were processed

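Total RNA of 8 cultures was measured on Affymetrix HG-U133 Plus 2.0 arrays, 1 array per culture. The cultures were HCT116 human colorectal carcinoma cells carrying wild-type KRAS or KRAS G13D, each kept in 1 mM or 25 mM glucose, with 2 independent replicates in each of the 4 groups. Per the labels' protocols the cells spent 7 days in their medium with a passage on day 3, and the medium of the low-glucose cultures was changed daily. Groups and replicate numbers were taken from the sample titles.

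The table of values deposited by the authors holds 54675 probe sets on 8 arrays, on a log scale. The base is not stated in the sources used here and was taken as log2 for the deposited values, so each fold given rests on that base. Each probe set had been centred on its median over the 8 arrays: the largest absolute median was 7.02e-07. No signal level is therefore left in the table, only differences between arrays, and the signal over background behind a value is unknown. The submitters' processing notes name MAS5, an algorithm that summarises probe sets. Its role, and any scaling or filtering before the centring, are not given in the sources used here. Array medians lay between −0.0087 and 0.0143. The SD over probe sets was 0.26 to 0.264 on the high-glucose arrays and 0.299 to 0.412 on the low-glucose arrays.

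Of the probe sets, 41097 named exactly 1 gene in the platform's annotation, 1801 named several and 11777 named none. Symbols of 41043 of the 1-gene probe sets were updated through Entrez identifiers with a table of the GRCh38.p14 assembly, which was used only for names and for which genes neighbour each other. No coordinates are given because the build behind the annotation is not named. Probe sets of XIST, TSIX and Y-linked genes (59) were left out. A gene's value was the mean of its 1-gene probe sets, which gave 19740 genes, 10511 of them with more than 1 probe set. KRAS itself had no 1-gene probe set by name and is not analysed here, and the same holds for TP53.

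The design chosen before the data were examined expected uncentred signals. Centring made 4 of its steps impossible: the pseudocount, the filter on low values, the choice of the brightest probe set of a gene and a variance trend over signal level. The mean of a gene's probe sets, listed beforehand as another choice, therefore replaced the brightest probe set, and no filter or pseudocount was applied. The variance prior was fitted without a trend, also listed beforehand as another choice.

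Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 8 arrays, with 4 group means and no replicate block. The fit left 4 residual degrees of freedom, to which the prior added 3.84, with a prior SD of 0.123. All groups shared 1 estimate of the spread per gene because a pair of arrays alone gives 1 degree of freedom. Errors are standard errors from this fit. The contrasts were low minus high glucose in each line, the difference between those responses, G13D minus wild type at each glucose level, and the mean of each factor over the other. Genes with a Benjamini-Hochberg adjusted p below 0.05 over all 19740 genes were called. The number of arrays limits the precision, and p-values measure the spread between cultures of 1 line per genotype.

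The 28 gene lists fixed beforehand were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists of a contrast. They covered sugar and central metabolism (glycolysis, MondoA/ChREBP targets, pentose phosphate, tricarboxylic acid cycle, oxidative phosphorylation, hexosamine and N-glycan precursors, cholesterol and fatty acid synthesis). Stress lists covered ATF4 targets, aminoacyl-tRNA synthetases, ER chaperones, hypoxia, NRF2, autophagy and lysosome, and FOXO targets. Signalling and growth lists covered ERK output, KRAS-associated secreted factors, G1/S, mitosis, p53, interferon-stimulated and NF-kB genes, ribosomal proteins, and ribosome biogenesis. Identity lists covered colon differentiation, Wnt targets, epithelial-mesenchymal markers, and markers of fibroblasts, endothelium and leukocytes. Of 608 distinct members, 551 (90.6%) were measured. Members were also adjusted over the list alone, and camera was rerun with an estimated correlation. Some lists share members, such as CDKN1A in the p53 and FOXO lists and CXCL8 in the NF-kB and KRAS-associated lists.

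Genes were named by a rule fixed beforehand. It took the 10 largest rises and 10 largest falls of each contrast between a pair of groups, among called genes whose arrays did not overlap between the groups. For the difference between responses it took the 5 smallest p-values in each direction. It added, for each list, called members and up to 4 members with the smallest p, and a fixed set (SLC2A1, TXNIP, ASNS, DDIT3, HSPA5, HMGCS1 and DUSP6, with KRAS) whatever their values.

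The steps were tested on simulated values for the glucose comparison in wild-type cells, over 19740 genes with 200 changed and the ribosomal protein list raised by log2 0.5. The test recovered 78% of changes of log2 1 and 97% of changes of log2 2. It made 7 false calls among 197, where called members of the raised list counted as true. The simulation gave a gene the same independent spread on all arrays. The real low-glucose replicates spread more than the high-glucose ones, so these rates may not hold for the glucose comparisons. Alternatives were quantile normalization, median centring, a replicate block, only the arrays of the groups compared, and each array left out in turn. Added after the data were seen were other choices of probe sets, an SD filter at the 40th percentile, array weights, a replicate term in low glucose, and fits without both low-glucose arrays of 1 number. The variance trend of the planned test was run as an alternative. It could follow only the mean of the centred values, which is not a signal level. In each fit that leaves out 1 array, the lone array of its group is assumed to vary like the other groups. Other pseudocounts and level filters, listed beforehand, were not tried, for the reason given above.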

Results

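Expression was measured in 8 cultures of HCT116 cells, a human colorectal carcinoma line, in a factorial design of KRAS genotype and glucose. KRAS is a small GTPase that relays growth factor signals, and G13D is an activating substitution found in colorectal cancer. Each line was kept for 7 days in 25 mM glucose or in 1 mM glucose, and 2 independent replicate cultures of each of the 4 groups were profiled on separate arrays. The deposited values carry no signal level, so all results are differences on the log2 scale and folds derived from them. Replicates were closer in high than in low glucose. The SD over genes of the difference between replicates was 0.152 in wild-type and 0.180 in G13D cells in high glucose, against 0.319 and 0.295 in low glucose. In high glucose 1 gene differed 2-fold or more between replicates in each line, while in low glucose 282 did in wild-type and 174 in G13D cells.

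The response to low glucose was first examined in wild-type cells. TP53I3, a p53-induced oxidoreductase, rose 14.9-fold (log2 3.90 ± 0.30 SE, n = 2 per group, limma adjusted p = 0.000725), the largest rise among called genes. LCN2, a secreted siderophore-binding protein, rose 9.18-fold (log2 3.20 ± 0.15, limma adjusted p = 0.000186), the laminin subunit gene LAMB3 10.1-fold (3.33 ± 0.31) and the chemokine gene CCL20 8.48-fold (3.08 ± 0.34). The fatty acid hydroxylase gene CYP4F3 rose by a log2 of 3.37 ± 0.29 and keratin KRT15 by 2.48 ± 0.23. Among falls, PRKAR2B, a regulatory subunit of protein kinase A, changed by −2.62 ± 0.17, WDR76 by −2.21 ± 0.13 and the mitotic kinase gene NEK2 by −2.19 ± 0.10 (limma adjusted p = 0.000186). The chemokine gene CXCL8 rose by 3.53 ± 0.61, while CYP24A1, which inactivates vitamin D, changed by −3.00 ± 0.53 and the mitochondrial gene ND6 by −2.72 ± 0.43. In limma 1674 of 19740 genes were called, 603 higher and 1071 lower in low glucose, of which 174 rose and 313 fell 2-fold or more. Without high-glucose wild-type replicate 1 the count was 387, and without replicate 2 it was 356. CXCL8, CYP24A1 and ND6 lost their calls in both of these fits, and over the 8 fits that each omit 1 array their values ran from 2.72 to 4.35, −3.97 to −2.02 and −3.40 to −2.04. With a replicate term in low glucose, where the low-glucose value is that of replicate 1, the count was 3727. Fits without both low-glucose arrays of 1 number also called more genes, with a spread from the high-glucose replicates alone.

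Proliferation genes fell together in wild-type cells. Of 30 measured genes of the G1/S and DNA replication list, 26 fell, or all 30 when adjusted over the list alone, with a median of −1.22 (camera adjusted p = 1.24e-31, adjusted p = 0.107 with an estimated correlation). The replicative helicase subunit MCM3 changed by −1.81 ± 0.10, UHRF1, which maintains DNA methylation, by −1.95 ± 0.12 and cyclin CCNE2 by −2.03 ± 0.23. Of 30 mitosis genes 27 fell, or all 30 adjusted over the list alone, with a median of −1.52 (camera adjusted p = 4.64e-29, adjusted p = 0.33 with an estimated correlation). Examples were the kinesin gene KIF20A (−2.16 ± 0.21) and the centromeric histone gene CENPA (−1.72 ± 0.13). Of 23 p53 targets 12 rose and none fell, or 17 rose adjusted over the list alone, with a median of 0.90 (camera adjusted p = 1.09e-16, adjusted p = 0.255 with an estimated correlation). The death receptor gene FAS rose by 2.02 ± 0.14, ZMAT3 by 1.79 ± 0.12, the cyclin-dependent kinase inhibitor gene CDKN1A by 1.64 ± 0.21 and MDM2, the ubiquitin ligase of p53, by 1.36 ± 0.10. Each of these lists and genes kept its call in all 8 fits that omit 1 array.

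Genes of protein folding in the endoplasmic reticulum (ER) rose in the same cells. Of 26 ER chaperone and unfolded protein response genes 15 rose and none fell, or 21 rose adjusted over the list alone, with a median of 1.07 (camera adjusted p = 2.02e-17, adjusted p = 0.337 with an estimated correlation). The chaperone genes HSPA5 and HSP90B1 rose by 1.91 ± 0.31 and 1.31 ± 0.17, the calcium-binding chaperone CALR by 1.27 ± 0.17 and CRELD2 by 1.47 ± 0.11. HSPA5 lost its call without either high-glucose wild-type array, and HSP90B1 and CALR without replicate 2 of that group. Over the 8 fits their values ran from 1.46 to 2.37, 1.21 to 1.41 and 1.03 to 1.51. Of 31 ATF4 and amino acid response genes 3 rose, or 6 adjusted over the list alone, with a median of 0.37 (camera adjusted p = 7.69e-05, adjusted p = 0.519 with an estimated correlation). That call ended without low-glucose wild-type replicate 1, where the median was 0.07, against 0.78 without replicate 2. DDIT3, a stress-induced transcription factor of this list, differed by 2.27 ± 1.45 (limma adjusted p = 0.46) and ASNS, asparagine synthetase, by 0.61 (limma adjusted p = 0.062), and was called without low-glucose wild-type replicate 2 (0.78). Of 17 aminoacyl-tRNA synthetase genes 2 rose over all genes and adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.0047, adjusted p = 0.474 with an estimated correlation). Its call also ended without low-glucose wild-type replicate 1 (0.18), and its median was 0.54 without replicate 2.

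Some inflammatory and secreted factors rose as well, though most members of these lists did not pass. Of 17 NF-kB targets 6 rose, or 10 adjusted over the list alone, with a median of 0.52 (camera adjusted p = 1.67e-07, adjusted p = 0.337 with an estimated correlation), including the NF-kB subunit gene RELB (1.65 ± 0.19). Of 17 KRAS-associated secreted and epithelial genes 5 rose, or 9 adjusted over the list alone, with a median of 0.61 that was 0.32 without low-glucose wild-type replicate 1 (camera adjusted p = 7.25e-05, adjusted p = 0.35 with an estimated correlation). The urokinase gene PLAU rose by 2.34 ± 0.30 and its receptor gene PLAUR by 1.48 ± 0.13. Of 23 interferon-stimulated genes 7 rose and 1 fell, or 11 and 2 adjusted over the list alone, with a median of 0.28 (camera adjusted p = 1.39e-05, adjusted p = 0.107 with an estimated correlation), among them IFIT3 (1.95 ± 0.15) and IFI27 (1.57 ± 0.18). Of 21 hypoxia-response genes 3 rose and 1 fell, or 7 and 1 adjusted over the list alone, with a median of 0.28 (camera adjusted p = 0.0036, adjusted p = 0.337 with an estimated correlation).

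A further 5 lists, 3 of them metabolic, were called in wild-type cells with medians from −0.19 to 0.31. Of 17 hexosamine and N-glycan precursor genes 2 rose, or 7 rose and 1 fell adjusted over the list alone, with a median of 0.31 (camera adjusted p = 0.012, adjusted p = 0.358 with an estimated correlation). The 30 oxidative phosphorylation genes had a median of −0.13 with 0 called in limma over all genes or over the list alone (camera adjusted p = 0.0037, adjusted p = 0.358 with an estimated correlation). Of 15 tricarboxylic acid cycle genes 1 rose and 1 fell, or 1 and 4 adjusted over the list alone, with a median of −0.19 (camera adjusted p = 0.0318, adjusted p = 0.346 with an estimated correlation). Of 17 NRF2 targets 2 rose, or 4 rose and 1 fell adjusted over the list alone, with a median of 0.22 (camera adjusted p = 0.0241, adjusted p = 0.358 with an estimated correlation). Of 23 ribosomal protein genes 1 rose over all genes and over the list alone, with a median of 0.07 (camera adjusted p = 0.0272, adjusted p = 0.337 with an estimated correlation). All 5 calls ended without low-glucose wild-type replicate 1 (medians 0.26, −0.10, −0.16, 0.26 and 0.07, in the order given). The tricarboxylic acid and ribosomal protein calls also ended without replicate 2 of that group (−0.23 and 0.07) and without high-glucose replicate 2 (−0.23 and 0.08), as did the NRF2 call in the latter fit (0.21). The NRF2 median was 0.37 without low-glucose replicate 2.

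The other 13 lists were not called in wild-type cells. Of 21 glycolysis genes 1 rose and 1 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.236), and the glucose transporter gene SLC2A1 differed by 0.28 (limma adjusted p = 0.33). Among 12 MondoA and ChREBP targets 2 rose, as over the list alone (camera adjusted p = 0.234), with TXNIP at 0.06 (limma adjusted p = 0.83). Cholesterol synthesis (2 of 18 genes rose and 1 fell, 5 and 2 adjusted over the list alone), fatty acid synthesis (1 of 11 rose, 2 adjusted over the list alone) and the pentose phosphate pathway (1 of 9 rose and 2 fell, 1 and 3 adjusted over the list alone) gave camera adjusted p of 0.156, 0.255 and 0.49. HMGCS1, which opens the mevalonate pathway, differed by 0.40 (limma adjusted p = 0.27). Of 28 ERK output genes 6 rose and 4 fell (10 and 6 adjusted over the list alone; camera adjusted p = 0.0803), and the ERK phosphatase gene DUSP6 differed by −0.94 ± 0.35 (limma adjusted p = 0.17). Of 19 FOXO targets 5 rose and 1 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.0961), of 22 autophagy and lysosome genes 2 rose and 1 fell (5 and 1; 0.225), and of 20 ribosome biogenesis genes 1 fell (1 over the list alone; 0.806). Without low-glucose wild-type replicate 2 the ERK, FOXO, autophagy and ribosome biogenesis lists were called, with medians of 0.15, 0.49, 0.10 and −0.19. The ribosome biogenesis median turned to 0.10 without both low-glucose arrays numbered 1, so its direction depended on the arrays kept. The FOXO list was also called without either low-glucose G13D array (0.36), and the colon differentiation list without high-glucose wild-type replicate 1 (0.12). Colon differentiation genes (2 of 25 rose, 1 fell, the same over the list alone), Wnt targets (3 of 18 fell, 2 rose and 5 fell over the list alone) and epithelial-mesenchymal markers (3 of 17 fell, the same over the list alone) gave camera adjusted p of 0.0928, 0.237 and 0.354. Markers of fibroblasts, endothelium and leukocytes had a median of 0.02, with 0 of 23 called in limma over all genes or over the list alone (camera adjusted p = 0.51), where 4119 of all genes had an unadjusted p below 0.05.

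The same comparison was made in G13D cells. NIBAN1, a stress-responsive gene, rose 7.78-fold (log2 2.96 ± 0.32 SE, n = 2 per group, limma adjusted p = 0.013). PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, rose by a log2 of 2.24 ± 0.29, the calcium-binding protein gene S100A14 by 2.23 ± 0.25, PLAU by 2.18 ± 0.30 and annexin ANXA3 by 2.07 ± 0.13 (limma adjusted p = 0.0026). ND6 changed by −2.59 ± 0.43, the RNA-binding protein gene RBM24 by −2.45 ± 0.29, the dehydrogenase gene DHRS2 by −2.07 ± 0.19 and the guidance receptor gene ROBO1 by −1.79 ± 0.09 (limma adjusted p = 0.0013). Epithelial adhesion genes CLDN7 and CDH1 rose by 1.33 ± 0.10 and 1.13 ± 0.18, and the hyaluronan receptor gene CD44 by 1.02 ± 0.13. In limma 313 genes were called, 158 higher and 155 lower, of which 59 rose and 37 fell 2-fold or more. The count was 734 with quantile normalization and 2408 with a replicate term in low glucose, each fewer than in wild-type cells under the same choice (1660 and 3727). With that term the low-glucose value is that of replicate 1. Fits without both low-glucose arrays of 1 number also called fewer genes than in wild-type cells, with a spread from the high-glucose replicates alone. The count was 681 without either low-glucose wild-type array and 16 without either high-glucose wild-type array, which enter only through the shared spread. It was 58 without low-glucose G13D replicate 1, and 19 and 0 without high-glucose G13D replicates 1 and 2 (limma, with 1758 genes at an unadjusted p below 0.05 in the fit that called 0). All of the 38 called genes that the naming rule took lost their call without at least 1 high-glucose array. NIBAN1, S100A14, PCK2, PLAU, ND6, CDH1 and CD44 did so without any 1 of the 4, and the last 5 also without low-glucose G13D replicate 1. Their values ran from 2.53 to 3.39, 1.85 to 2.61, 1.96 to 2.51, 1.82 to 2.54, −3.05 to −2.13, 1.01 to 1.25 and 0.88 to 1.16. RBM24 lost its call without either high-glucose wild-type array or G13D replicate 2 (−2.85 to −2.05). For ANXA3, DHRS2, ROBO1 and CLDN7 only the fit without G13D replicate 2 ended it, with values of 1.91 to 2.23, −2.35 to −1.79, −1.84 to −1.73 and 1.28 to 1.38 over the 8 fits.

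ER chaperones led the gene lists in G13D cells. Of 26 members 6 rose and none fell, or 13 rose adjusted over the list alone, with a median of 0.59 that was 0.38 and 0.93 without low-glucose G13D replicates 1 and 2 (camera adjusted p = 3.78e-11, adjusted p = 0.583 with an estimated correlation). CRELD2 rose by 1.38 ± 0.11, HSP90B1 by 1.44 ± 0.17 and the disulfide isomerase gene PDIA4 by 1.15 ± 0.14, while HSPA5 differed by 1.24 ± 0.31 (limma adjusted p = 0.10, and 0.0273 without either low-glucose wild-type array). CRELD2 lost its call without high-glucose G13D replicate 2 (1.33 to 1.44 over the 8 fits). HSP90B1 and PDIA4 lost theirs without any 1 of the high-glucose arrays or low-glucose G13D replicate 1 (1.22 to 1.66 and 1.05 to 1.25), as did NEK2 of the mitosis list (−0.82 to −0.73). Of 30 mitosis genes 1 fell, NEK2 (−0.77 ± 0.10), or 8 adjusted over the list alone, with a median of −0.50 that was −0.29 without low-glucose replicate 1 (camera adjusted p = 7.53e-10, adjusted p = 0.583 with an estimated correlation). Of 30 G1/S genes 0 were called in limma, or 1 fell adjusted over the list alone, with a median of −0.23 (camera adjusted p = 4.00e-06, adjusted p = 0.583 with an estimated correlation), where 2790 of all genes had an unadjusted p below 0.05. The G1/S median was −0.12 without low-glucose replicate 1 and −0.14 without high-glucose replicate 1. With quantile normalization 6 mitosis genes fell and 11 ER chaperones rose. Fits without both low-glucose arrays of 1 number also called more of both than the fit of all arrays, with a spread from the high-glucose replicates alone. The 23 p53 targets had a median of 0.03 with 0 called in limma over all genes or over the list alone (camera adjusted p = 0.946), CDKN1A at 0.76 ± 0.21 (limma adjusted p = 0.13) and TP53I3 at 0.12 ± 0.30. Without both low-glucose arrays of 1 number, and by that high-glucose spread, some p53 targets were called as risen and others as fallen.

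A further 6 lists were called in G13D cells, and each call ended without 1 array. Of 31 ATF4 targets 1 rose over all genes and over the list alone, ASNS by 0.87 ± 0.16, with a list median of 0.49 (camera adjusted p = 9.79e-05, adjusted p = 0.646 with an estimated correlation). ASNS went the same way in 1 of its 2 probe sets and lost its call without any 1 of the high-glucose arrays or low-glucose G13D replicate 1 (0.73 to 1.02 over the 8 fits), and DDIT3 differed by 1.74 ± 1.45 (limma adjusted p = 0.71). Of 17 aminoacyl-tRNA synthetase genes 1 rose, or 5 adjusted over the list alone (median 0.34, camera adjusted p = 0.000541, adjusted p = 0.583 with an estimated correlation). Of 17 KRAS-associated secreted genes 3 rose, or 4 adjusted over the list alone (median 0.32, camera adjusted p = 0.000288, adjusted p = 0.583 with an estimated correlation). Of 28 ERK output genes 4 rose, or 9 rose and 3 fell adjusted over the list alone (median 0.20, camera adjusted p = 0.0145, adjusted p = 0.583 with an estimated correlation). Hexosamine genes (median 0.17, camera adjusted p = 0.00211, adjusted p = 0.583 with an estimated correlation) and cholesterol synthesis genes (median 0.16, camera adjusted p = 0.0324, adjusted p = 0.646 with an estimated correlation) had 0 members called in limma over all genes or over the list alone. Without low-glucose G13D replicate 1 the ATF4, synthetase, secreted, ERK and hexosamine calls ended, with medians of 0.13, 0.14, 0.11, 0.10 and 0.07. Without replicate 2 the medians of the ATF4, synthetase and secreted lists were 0.89, 0.60 and 0.51. The ERK call also ended without high-glucose replicate 1 (0.22), and the cholesterol call ended without low-glucose replicate 2 (0.07) and high-glucose replicate 2 (0.08), with 0.27 without high-glucose replicate 1. Among interferon-stimulated genes 1 of 23 fell, IFIT1 (−1.53 ± 0.25), also over the list alone (camera adjusted p = 0.0796). IFIT1 kept its call only without a low-glucose wild-type array (−1.83 to −1.24 over the 8 fits).

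The responses of the lines, which share no arrays but were tested with the same spread per gene, were compared gene by gene. Both lines raised 100 genes and lowered 106, or 206 in the same direction, against 4.83 and 8.41 for independent lists, and 2 genes were called in opposite directions. The counts for independent lists ignore the shared spread. They also ignore that same-numbered low-glucose cultures of the lines varied together (r = 0.497 across genes), so they may be too low. Among genes raised in both, LAMB3 rose by 3.33 ± 0.31 in wild-type and 1.86 ± 0.31 in G13D cells, and CRELD2 by 1.47 ± 0.11 and 1.38 ± 0.11. Of the 313 genes called in G13D cells 294 had the same sign in wild-type cells, and the correlation of the responses across all genes, which are not independent replicates, was 0.599. The shared count was 403 without low-glucose wild-type replicate 2, 9 without either high-glucose wild-type array and 39 without low-glucose G13D replicate 1. It was 12 and 0 without high-glucose G13D replicates 1 and 2, the last of these being the fit in which limma called 0 genes in G13D cells and 1758 had an unadjusted p below 0.05.

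**Figure D1:**
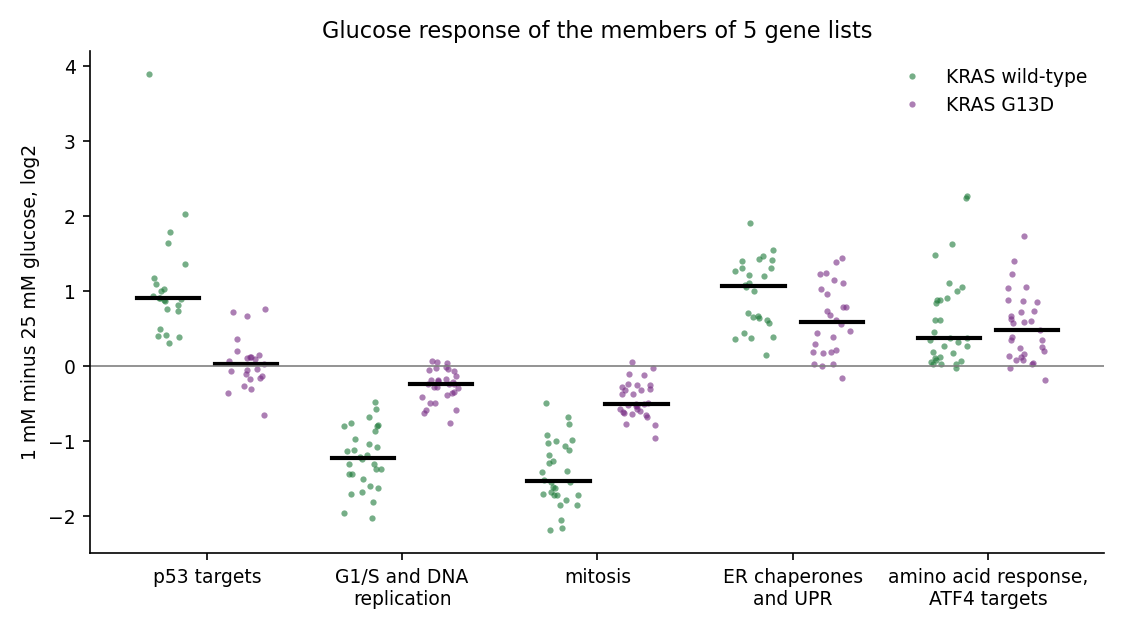
Response to low glucose (log2, low minus high) of each measured member of 5 gene lists in wild-type and G13D cells, with 1 point per gene and black bars at the medians. In wild-type cells the G1/S and mitosis medians lie at −1.22 and −1.52 and the p53 median at 0.90, against −0.23, −0.50 and 0.03 in G13D cells, while the ATF4 medians are 0.37 and 0.49.

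The difference between the responses was tested directly (G13D minus wild type). Responses are signed (low minus high glucose), so a higher response can be a smaller fall and a lower response a larger fall. LCN2 had the largest negative difference among the genes of smallest p, −3.10 ± 0.21 on the log2 scale (limma adjusted p = 0.0057, n = 2 per group). The interferon-induced gene TRIM22 differed by −2.31 ± 0.16, ROBO1 by −1.80 ± 0.13, C1orf116 by −1.78 ± 0.14 and SUGCT by −1.93 ± 0.15. In the other direction the bile acid synthesis oxidase gene ACOX2 differed by 1.46 ± 0.13 (limma adjusted p = 0.0098), SOWAHA by 1.79 ± 0.16, MCM3 by 1.53 ± 0.14, the kisspeptin receptor gene KISS1R by 1.80 ± 0.16 and the inositol phosphatase gene IMPA2 by 1.48 ± 0.14. Limma called 59 genes, 33 with a higher and 26 with a lower response in G13D cells. With quantile normalization the split was 19 and 24. The count was 3 with a variance trend and 554 with a replicate term in low glucose. The trend was part of the planned test, but here it could follow only the mean of centred values. Without low-glucose wild-type replicate 2 the count was 304, and it was 16 and 38 without low-glucose G13D replicates 1 and 2. Without any 1 of the 4 high-glucose arrays limma called 0 genes, with 1176 and 1055 genes (wild-type replicates 1 and 2) and 1396 and 1229 genes (G13D replicates 1 and 2) at an unadjusted p below 0.05. In those fits every gene named here lost its call, while over all 8 fits LCN2 ran from −3.32 to −2.89 and MCM3 from 1.45 to 1.61.

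By list, cell cycle and p53 genes differed between the responses. The G1/S and mitosis lists had medians of −1.22 and −1.52 in wild-type cells and −0.23 and −0.50 in G13D cells. Their higher response in G13D cells was therefore a smaller fall. Of 30 G1/S genes 5 had a higher response in G13D cells, or 27 adjusted over the list alone, with a median of 0.92 (camera adjusted p = 1.05e-33, adjusted p = 0.0958 with an estimated correlation). Besides MCM3 these were UHRF1 (1.46 ± 0.18), MCM2 (1.46 ± 0.18), RFC4 (1.20 ± 0.17) and TK1 (0.98 ± 0.13). Of 30 mitosis genes 1 did, NEK2 (1.42 ± 0.15), or 23 adjusted over the list alone, with a median of 1.00 that was 0.66 without low-glucose wild-type replicate 1 (camera adjusted p = 5.63e-26, adjusted p = 0.311 with an estimated correlation). Of 23 p53 targets 5 had a lower response in G13D cells, or 12 adjusted over the list alone, with a median of −0.86 (camera adjusted p = 7.61e-22, adjusted p = 0.161 with an estimated correlation). They were TP53I3 (−3.78 ± 0.43), FAS (−2.07 ± 0.20), ZMAT3 (−1.85 ± 0.17), MDM2 (−1.34 ± 0.15) and RRM2B (−1.14 ± 0.15). Of 23 interferon-stimulated genes 2 were lower, IFIT3 (−1.80 ± 0.22) and IFIT2 (−1.27 ± 0.16), or 9 lower and 1 higher adjusted over the list alone, with a median of −0.45 that was −0.28 without low-glucose wild-type replicate 1 (camera adjusted p = 1.94e-11, adjusted p = 0.0424 with an estimated correlation). This was the only list call in the 5 contrasts described that held with an estimated correlation. With quantile normalization 1 G1/S, 0 mitosis and 3 p53 genes were called in limma, with medians of 0.70, 0.80 and −0.50, where 43 genes were called in all and 1633 had an unadjusted p below 0.05. More members were called without both low-glucose arrays of 1 number. The spread there comes from the high-glucose replicates alone, so those calls leave out the spread between low-glucose cultures. The calls of these 4 lists held in all 8 fits that omit 1 array. Those of the genes named here ended without any 1 of the high-glucose arrays, and all but those of MCM3, FAS and ZMAT3 also without low-glucose G13D replicate 1. TP53I3, IFIT3, MCM2, RFC4, TK1 and RRM2B lost theirs without low-glucose G13D replicate 2 too, and TK1 and RRM2B also without low-glucose wild-type replicate 1. Over the 8 fits TP53I3 lay between −4.29 and −3.26, ZMAT3 between −1.99 and −1.71 and UHRF1 between 1.34 and 1.58.

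A further 4 lists were called in this difference. Of 17 NF-kB targets 1 had a lower response in G13D cells, TNFAIP2 (−0.96 ± 0.13), or 6 adjusted over the list alone, with a median of −0.63 (camera adjusted p = 7.44e-09, adjusted p = 0.358 with an estimated correlation). That median was −0.24 without low-glucose wild-type replicate 1 and −0.34 without low-glucose G13D replicate 2. TNFAIP2 kept its call in 1 of the 8 fits that omit 1 array (−1.02 to −0.91), the fit without low-glucose wild-type replicate 2. Of 17 NRF2 targets 1 was lower, the aldo-keto reductase gene AKR1B10 (−1.73 ± 0.22), or 3 adjusted over the list alone, with a median of −0.29 that was −0.19 without high-glucose wild-type replicate 2 (camera adjusted p = 0.000166, adjusted p = 0.311 with an estimated correlation). AKR1B10 lost its call without any 1 of the high-glucose arrays or low-glucose G13D replicate 1 (−1.88 to −1.59). ER chaperones had a median of −0.25 with 0 of 26 members called in limma over all genes or over the list alone, where 1678 of all genes had an unadjusted p below 0.05 (camera adjusted p = 3.85e-05, adjusted p = 0.748 with an estimated correlation). That call ended without low-glucose wild-type replicate 1 (−0.03) and low-glucose G13D replicate 2 (−0.16), and the median was −0.55 and −0.47 without the other low-glucose array of each line. Tricarboxylic acid cycle genes had a median of 0.13 with 0 of 15 called in limma, or 1 higher adjusted over the list alone (camera adjusted p = 0.0489, adjusted p = 0.415 with an estimated correlation). Their call held only without low-glucose G13D replicate 2 (0.22), and the other 7 fits gave medians from 0.09 to 0.20. ATF4 targets had a median difference of −0.02 (camera adjusted p = 0.598), whose sign depended on single low-glucose arrays. It was 0.40 without wild-type replicate 1 (camera adjusted p = 0.0435), −0.45 without wild-type replicate 2 and −0.44 without G13D replicate 1, each of these called.

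**Figure D2:**
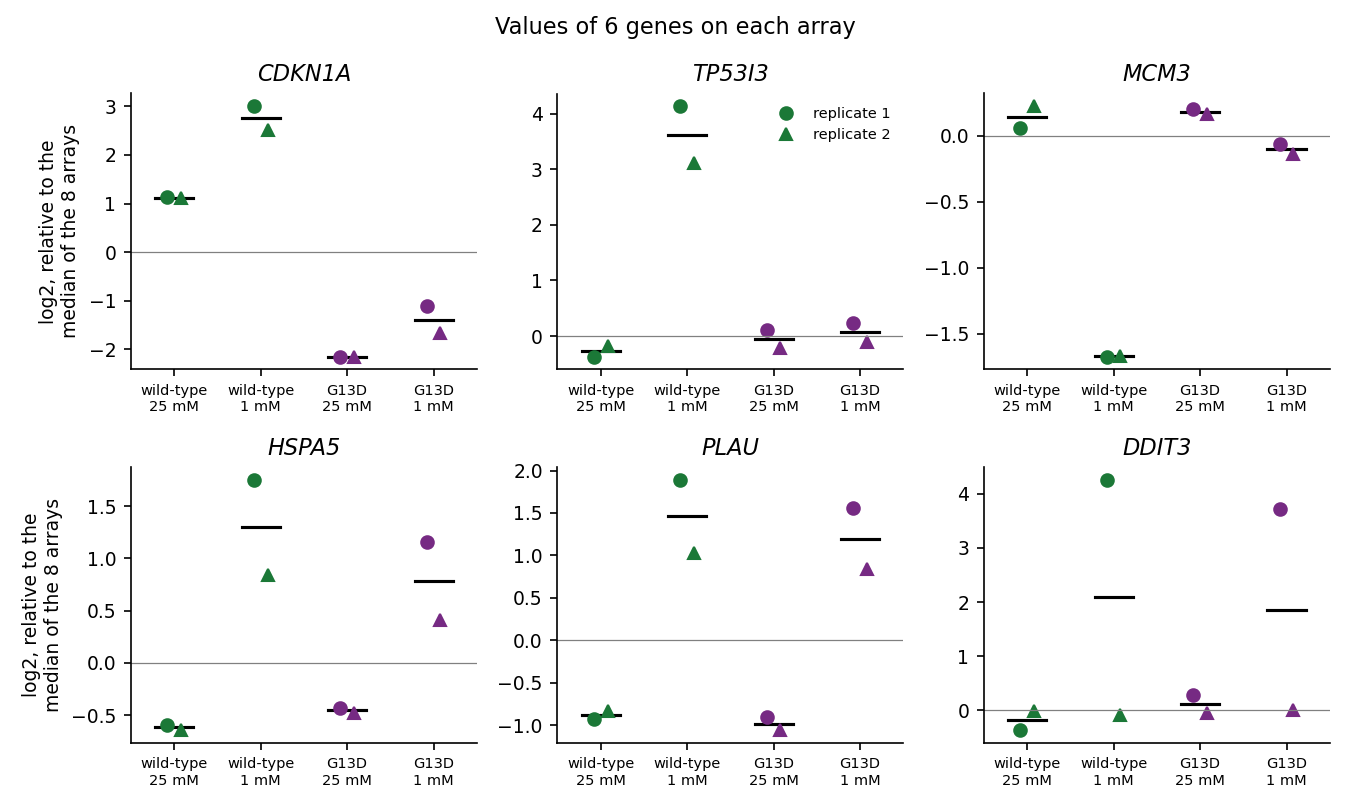
Values of 6 genes on each of the 8 arrays (log2 relative to the gene's median over the arrays; circles replicate 1, triangles replicate 2, black lines group means). CDKN1A, TP53I3, MCM3, HSPA5 and PLAU separate groups, while DDIT3 stands at 4.26 and 3.71 on replicate 1 and at −0.10 and 0.004 on replicate 2 of the low-glucose wild-type and G13D cultures.

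The lines were then compared with each other in high glucose. MAL2, a transport protein of polarized epithelia, was 186-fold lower in G13D than in wild-type cells (log2 −7.54 ± 0.20 SE, n = 2 per group, limma adjusted p = 1.4e-06). Keratin KRT23 was 69.2-fold lower (−6.11 ± 0.19), and ADIRF (−5.82 ± 0.13), the cytokine gene TNFSF4 (−5.42 ± 0.13), the stem cell surface marker PROM1 (−5.40 ± 0.14) and the Wnt receptor ligase gene RNF43 (−4.25 ± 0.15) were also lower. MLLT11 was 61.7-fold higher in G13D cells (5.95 ± 0.20, limma adjusted p = 3.7e-06), ROBO1 27.6-fold higher (4.79 ± 0.09) and the collagen gene COL6A3 higher by 3.65 ± 0.23. PHGDH, the entry enzyme of serine synthesis, was 11.4-fold lower (−3.51 ± 0.27) and squalene epoxidase SQLE differed by −2.10 ± 0.10. Limma called 1249 genes, 553 higher and 696 lower in G13D cells, of which 125 and 290 differed 2-fold or more. Quantile normalization gave 2318 genes, array weights 2617 and a fit of only the arrays compared 3036. The count was 357 and 369 without high-glucose wild-type replicates 1 and 2, and 414 and 425 without high-glucose G13D replicates 1 and 2. All genes named here kept their calls in these fits.

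Of 23 p53 targets 6 were lower in G13D cells in high glucose, or 10 adjusted over the list alone, with a median of −0.58 (camera adjusted p = 1.57e-10, adjusted p = 0.923 with an estimated correlation). With quantile normalization 11 were lower (median −0.66), and without both low-glucose arrays of either number 16 were. CDKN1A was 9.63-fold lower (−3.27 ± 0.21, limma adjusted p = 0.000108), and ZMAT3 and RRM2B were lower, at −1.18 ± 0.12 and −0.86 ± 0.11. Of 28 ERK output genes 6 were lower and 1 higher, the same adjusted over the list alone, with a median of −0.09 (camera adjusted p = 0.0472, adjusted p = 0.923 with an estimated correlation). The lower ones included the cytokine gene LIF (−1.77 ± 0.12) and the growth factor gene EREG (−2.06 ± 0.23), and the higher one was the transcription factor gene ETV4 (0.61 ± 0.13). LIF and EREG were also the members that were lower among 17 KRAS-associated secreted genes, with 3 lower adjusted over the list alone and a median of −0.12 (camera adjusted p = 0.0149, adjusted p = 0.923 with an estimated correlation). The ERK call ended without high-glucose wild-type replicate 2 (−0.03) and G13D replicate 1 (−0.06), and the secreted call without G13D replicate 1 (−0.15), with −0.24 without wild-type replicate 2. ETV4 lost its call without G13D replicate 1 or either high-glucose wild-type array and ran from 0.45 to 0.78 over the 8 fits. DUSP6 differed by −0.80 ± 0.35 (limma adjusted p = 0.28). Among 17 epithelial-mesenchymal markers 3 were higher and 2 lower, the same over the list alone (camera adjusted p = 0.665), with the intermediate filament gene VIM higher by 1.75 ± 0.09 and SPARC lower (−1.39 ± 0.11). Epithelial CDH1 (−1.62 ± 0.18) and CD44 (−1.93 ± 0.13) were lower. Of 30 G1/S genes 1 was lower, also over the list alone (camera adjusted p = 0.867), and of 30 mitosis genes 2 were lower, or 3 adjusted over the list alone (camera adjusted p = 0.479).

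In low glucose the lines differed in 2847 genes in limma, 1714 higher and 1133 lower in G13D cells, of which 448 and 415 differed 2-fold or more. MAL2 was 292-fold lower (−8.19 ± 0.20 SE, n = 2 per group, limma adjusted p = 8.1e-07), and ADIRF (−6.98 ± 0.13) and KRT23 (−5.79 ± 0.19) were also lower. MLLT11 was 93.8-fold higher (6.55 ± 0.20), CYP24A1 higher by 3.93 ± 0.53 and COL6A3 by 3.96 ± 0.23. VIM was higher by 2.36 ± 0.09 and the transcription factor gene SNAI2 by 3.11 ± 0.35, and the immediate early gene FOS was higher by 1.66 ± 0.19. SLC2A1 was lower (−0.78 ± 0.14, limma adjusted p = 0.0091), while DDIT3 differed by −0.22. The called genes named here kept their calls in the 8 fits that omit 1 array, in which the count ran from 2064 to 2959. Which glucose level gave more genes depended on the fit. With only the arrays compared 1004 genes were called in low and 3036 in high glucose, with array weights 2080 and 2617, and with quantile normalization 2194 and 2318. With a replicate term in low glucose the order was kept, at 4586 in low and 2541 in high glucose.

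Of 23 p53 targets 20 were lower in G13D cells in low glucose, or 22 adjusted over the list alone, with a median of −1.59 (camera adjusted p = 1.37e-22, adjusted p = 0.193 with an estimated correlation). CDKN1A was 17.7-fold lower (−4.15 ± 0.21), and TP53I3 (−3.56 ± 0.30), ZMAT3 (−3.03 ± 0.12) and FAS (−2.65 ± 0.14) were also lower. Of 30 G1/S genes 23 were higher, or 29 adjusted over the list alone, with a median of 1.03 (camera adjusted p = 4.99e-18, adjusted p = 0.193 with an estimated correlation). MCM2 was higher by 1.65 ± 0.13 and MCM3 by 1.57 ± 0.10. Of 30 mitosis genes 18 were higher, or 22 adjusted over the list alone, with a median of 0.95 (camera adjusted p = 2.84e-12, adjusted p = 0.566 with an estimated correlation), among them NEK2 (1.76 ± 0.10) and the spindle checkpoint kinase gene TTK (1.42 ± 0.11). Of 23 interferon-stimulated genes 11 were lower and 2 higher, the same adjusted over the list alone, with a median of −0.38 that was −0.21 without low-glucose wild-type replicate 1 (camera adjusted p = 2.31e-06, adjusted p = 0.136 with an estimated correlation). IFIT1 was lower (−1.95 ± 0.25) and USP18, which restrains interferon signalling, higher (0.96 ± 0.12). Of 17 NF-kB targets 8 were lower, or 9 adjusted over the list alone, with a median of −0.50 (camera adjusted p = 2.34e-06, adjusted p = 0.556 with an estimated correlation), such as CCL20 (−2.99 ± 0.34). Of 17 NRF2 targets 4 were lower, or 9 adjusted over the list alone, with a median of −0.32 (camera adjusted p = 5.33e-05, adjusted p = 0.274 with an estimated correlation), including heme oxygenase HMOX1 (−1.26 ± 0.12).

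The other 3 lists called in low glucose lost their calls without 1 array. ER chaperones had a median of −0.22 with 1 of 26 lower over all genes and over the list alone (camera adjusted p = 0.00578, adjusted p = 0.758 with an estimated correlation). KRAS-associated secreted genes had a median of −0.26 with 5 of 17 lower, or 6 adjusted over the list alone (camera adjusted p = 0.00107, adjusted p = 0.566 with an estimated correlation). Autophagy and lysosome genes had a median of −0.17 with 1 of 22 higher and 4 lower, or 2 and 6 adjusted over the list alone (camera adjusted p = 0.0456, adjusted p = 0.674 with an estimated correlation). Without low-glucose wild-type replicate 1 the medians were 0.02, −0.05 and −0.03, and without low-glucose G13D replicate 2 they were −0.01, −0.19 and −0.10, with no call in either fit. Without wild-type replicate 2 they were −0.44, −0.74 and −0.26, and without G13D replicate 1 −0.43, −0.62 and −0.27. Markers of fibroblasts, endothelium and leukocytes had a median of 0.01 in low glucose, with 0 of 23 called in limma over all genes or over the list alone, where 5094 of all genes had an unadjusted p below 0.05.

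The lines differed in the same direction at both glucose levels in 948 genes, 436 higher and 512 lower in G13D cells, against 48.0 and 39.9 for independent lists, and in 5 genes in opposite directions. These comparisons share no arrays but use the same spread per gene, which by itself can raise the overlap above that of independent lists. Their correlation across genes, which are not independent replicates, was 0.788. Without high-glucose wild-type replicates 1 and 2 and G13D replicates 1 and 2 the shared count was 320, 329, 359 and 379. MAL2, KRT23, ADIRF, MLLT11 and COL6A3 were among the genes that differed at both levels. Averaged over the lines, low glucose changed 2407 genes in limma, 988 higher and 1419 lower, and averaged over glucose the lines differed in 3873 genes, 2298 higher and 1575 lower in G13D cells. The first of these counts was 1021 and 1062 without high-glucose wild-type replicates 1 and 2 and 1234 and 1139 without high-glucose G13D replicates 1 and 2. The genotype count was 2295 and 2424 without high-glucose wild-type replicates 1 and 2 and 2459 without high-glucose G13D replicate 1.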

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

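The tests of other differences between the lines, of a shared culture day or medium, of other cell types and of neighbouring genes were chosen after the results were seen, as were the fits without both low-glucose arrays of 1 number.

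Low glucose changed 59 genes by different amounts in the lines, by the test of the difference itself (G13D minus wild-type response). The list medians of the difference were −0.863 for p53 targets, 0.921 for G1/S and 1.005 for mitosis genes. In wild-type cells p53 targets rose and both cell cycle lists fell. In G13D cells both cell cycle lists also fell, but less (medians −0.23 for G1/S and −0.50 for mitosis), and the p53 median was 0.03. With an estimated correlation in camera, 0 lists were called in wild-type cells (smallest camera adjusted p = 0.107), and these lists were not called in the difference. Array scaling as the whole cause is argued against by quantile normalization, which gives all arrays the same spread and left the p53 median at −0.503 (spread 0.0731). That value only just passed the bound set beforehand. The normalization was run on centred values, so it evened out the spread of differences and not that of signals. The median moved from −0.863, so scaling as a part of the cause stays open. A single pair of low-glucose arrays as the whole cause is argued against by the fits without both arrays of 1 number, in which the p53 median nearer 0 was −0.621 (spread 0.185). Both spreads were resampled over the genes of the list, which are not independent, and do not measure the spread between cultures. A difference between the lines other than KRAS genotype cannot be told apart from the genotype, because 1 line stands for each and 34 genes differed 8-fold or more between them at both glucose levels. The p53 target CDKN1A was among them (G13D minus wild type −3.27 in high and −4.15 in low glucose). The p53 list was already lower in G13D cells in high glucose, with a median of −0.58. A difference in p53 targets that is present without low glucose is thus not separated from the response. A dependence of the glucose response of these lists on KRAS genotype may therefore be held only as an untested hypothesis.

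ATF4 targets differed between the low-glucose replicates of both lines: the list median of replicate 1 minus replicate 2 was 0.89 in wild-type and 0.70 in G13D cells, and 25 of 31 genes were higher on replicate 1 in both. DDIT3 was higher by 4.36 and 3.71, and other lists moved too in wild-type and G13D cells: ER chaperones (0.50 and 0.32), synthetases (0.32 and 0.40), p53 targets (0.50 and 0.21) and mitosis genes (−0.60 and −0.27). A different amount of labelled RNA is argued against in G13D cells, whose poly-A spike-in signals in low glucose were close (0.197 and 0.280 on replicates 1 and 2). The high-glucose G13D arrays, with signals of −0.650 and −0.137, differed in the ATF4 list by 0.00332. In wild-type cells it stays open, because the low-glucose signals were further apart (−0.153 and 0.905) than on those arrays. A shift of whole arrays is argued against by the median of all genes, of which the larger difference between low-glucose replicates was −0.0349. A culture day or medium shared by same-numbered low-glucose cultures is a candidate explanation: the differences between replicates correlated across genes between the lines with r = 0.497 in low glucose, against at most 0.0544 for the other pairs of groups. Separate biological causes in each culture were not tested.

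Some genes differed very strongly between the lines at both glucose levels, 34 of them 8-fold or more (9 higher and 25 lower in G13D cells), such as MAL2, KRT23 and MLLT11. Their 10 nearest measured genes shifted in the same direction by a median of 0.0197, with 0 of 34 reaching 0.4. This argues against a gain or loss of chromosome segments that moves most of these neighbours. Neighbours without expression cannot shift and cannot be recognised in centred values, so other gains or losses stay open. Fibroblasts, endothelial cells or leukocytes are argued against by their markers, taken type by type: the largest median was 0.161 (SD over markers 0.145, endothelial, high glucose). Fibroblast markers had medians of 0.0267 and 0.0118 in high and low glucose, although COL6A3 and VIM were higher in G13D cells. The highest fibroblast marker stood at 0.640 in high glucose (SD over markers 0.235), where 1 of 23 markers of all types was called higher. A sequence variant under single probe sets as the whole cause is argued against in a set picked by single probe sets with such differences (55 genes): of its 29 genes with several probe sets, 65.5% had a second one shifted by 1 or more the same way. Regional change of neighbouring genes stays open: 3 adjacent pairs (APOE and APOC1, LOC646736 and IRS1, CAMK2D and ARSJ) changed together 4-fold or more, against a median of 0 and a highest count of 3 in 1000 shuffles of gene positions (permutation p = 0.00699), which is rare by chance but concerns few genes. Cells of another epithelial type were not tested and, with clonal or genotype differences, may account for the genes that these values (0.161 for the markers) leave unexplained.

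The test of the difference between responses also picked out other lists and genes. The list medians were −0.2526 for ER chaperones, 0.1309 for tricarboxylic acid cycle enzymes, −0.4547 for interferon-stimulated genes, −0.6298 for NF-kB targets and −0.2885 for NRF2 targets. With an estimated correlation only the interferon-stimulated list kept its call. The ER call ended without low-glucose wild-type replicate 1 or low-glucose G13D replicate 2. Of the fits that omit 1 array, the tricarboxylic acid call held only without low-glucose G13D replicate 2. Genes with a higher signed response (low minus high glucose) in G13D cells were ACOX2 (1.463), SOWAHA (1.788), MCM3 (1.53), KISS1R (1.796) and IMPA2 (1.48). A higher signed response can be a smaller fall: IMPA2 changed by −2.08 in wild-type and −0.60 in G13D cells. Genes with a lower signed response in G13D cells were LCN2 (−3.105), TRIM22 (−2.314), ROBO1 (−1.802), C1orf116 (−1.777) and SUGCT (−1.928). ROBO1 fell in G13D cells, so a lower signed response need not be a weaker one.

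The poly-A spike-in probe sets, which no comparison used, stood above the high-glucose arrays on 3 low-glucose arrays. Their mean over 24 probe sets was 0.9054 on wild-type replicate 2, 0.1968 on G13D replicate 1 and 0.2795 on G13D replicate 2, against −0.650 to −0.00848 on the high-glucose arrays and −0.153 on low-glucose wild-type replicate 1.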

How the results depend on the processing

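The alternatives on probe sets, SD filter, array weights, the replicate term in low glucose and fits without both low-glucose arrays of 1 number were chosen after seeing the data. The variance trend, part of the planned test, was run as an alternative over the mean of centred values. Over the fits that omit 1 array, counts ran from 356 to 2214 (glucose, wild type), 0 to 681 (glucose, G13D), 0 to 304 (difference of responses), 357 to 1684 and 2064 to 2959 (genotype in high and low glucose), 1021 to 3243 and 2295 to 4190 (means for glucose and genotype). Overlaps ran from 0 to 403 (glucose) and 320 to 1118 (genotype). The fits that called 0 genes had 1055 to 1758 at an unadjusted p below 0.05 in limma. Quantile normalization gave 734 genes for glucose in G13D, 2318 for genotype in high glucose and 401 shared glucose genes. Fits of only the arrays compared gave 110 (glucose, G13D), 3036 and 1004 (genotype in high and low glucose), 362 and 1982 (means) and 66 (shared glucose genes). The difference of responses was 34 with the most variable probe set, 3 with a variance trend and 99 with array weights, which gave 2617 for genotype in high glucose. The replicate term in low glucose gave 3727, 2408 and 554 (glucose in wild type, in G13D, and their difference), 2541 and 4586 (genotype in high and low glucose), 4438 (mean glucose), and overlaps of 1667 and 1912. Its glucose responses, their mean and their overlap are those of low-glucose replicate 1 against high glucose, not of both replicates. Without both low-glucose arrays numbered 1, the counts were 2665, 1112 and 381 for glucose, 3036 for genotype in high glucose, and overlaps of 618 and 1721. Without both numbered 2, they were 4002, 2459 and 717 for glucose, 3036 for genotype in high glucose, 5114 for mean glucose, and overlaps of 1545 and 1810. Median centring, probe sets without suffix and the SD filter moved no count by over 1.5 times. With the replicate block the counts were 1766, 399 and 73 for glucose, 1270 and 2989 for genotype, 2611 and 3922 for the means and 259 and 980 for the overlaps, all within 1.5 times. The block assumes that a number means the same in all groups, which the values do not show: r of the difference between replicates was 0.497 between the lines in low glucose and −0.221 to 0.0544 for the other pairs of groups. With probe sets without suffix, values turned for P4HA1 (−0.0476), CENPF (0.0461), CDC25C (0.0277), FN1 (0.0449) and BTG1 (−0.0671) for glucose in wild type, ASNS (−0.0169) in G13D, CDC25C (0.0548) for genotype in high and RGS16 (0.34) and CENPF (−0.0077) in low glucose. Ribosome biogenesis turned for glucose in wild type without both low-glucose arrays numbered 1 (0.10, adjusted p = 0.0437, so called there), and the ATF4 list in the difference of responses without low-glucose wild-type replicate 1 (0.396, adjusted p = 0.0435, so called there; range over the fits −0.455 to 0.396, and −0.02 with all arrays, not called). The cause of these changes was not tested. Alternatives with pseudocounts of 1 and 64, no level filter and a stricter one were not run, because the values are centred. For the same reason no signal over background is known.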

Other observations

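The tests of splits of the arrays were planned; the genes named in the next 2 paragraphs were chosen after their values were seen.

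Low glucose raised and lowered further genes in both lines. C19orf33 rose by a log2 of 1.69 ± 0.13 in wild-type and 1.64 ± 0.13 in G13D cells, the chloride channel gene CLIC3 by 1.58 ± 0.19 and 1.70 ± 0.19, and the transmembrane gene TMC4 by 1.55 ± 0.19 and 1.64 ± 0.19. The noncoding gene LINC00973 rose by 2.13 ± 0.20 and 2.15 ± 0.20, the growth factor gene BTC by 1.34 ± 0.21 and 1.68 ± 0.21, and the complement regulator gene CD55 by 1.48 ± 0.15 and 1.12 ± 0.15. The ER exchange factor gene SIL1, which is in none of the fixed lists, rose by 1.34 ± 0.15 and 1.12 ± 0.15. Among genes lowered in both lines were the testis-enriched chaperone gene HSPA2 (−2.11 ± 0.22 and −1.45 ± 0.22), the DNA methyltransferase gene DNMT3B (−1.36 ± 0.19 and −1.13 ± 0.19) and the TGF-beta coreceptor gene TGFBR3 (−1.19 ± 0.16 and −1.52 ± 0.16). All were called in limma in both lines with n = 2 per group. Their calls in G13D cells ended without high-glucose G13D replicate 2, the fit in which limma called 0 genes and 1758 had an unadjusted p below 0.05.

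Among the genes 8-fold or more apart between the lines at both glucose levels, ZNF468 differed between G13D and wild-type cells by −4.15 ± 0.26 in high and −4.67 ± 0.26 in low glucose, ZNF600 by −4.09 ± 0.14 and −4.65 ± 0.14, ZNF83 by −4.15 ± 0.33 and −3.67 ± 0.33 and ZNF266 by −4.02 ± 0.11 and −4.19 ± 0.11. APOE, an apolipoprotein gene, was higher by 3.04 ± 0.10 and 3.38 ± 0.10, and the neighbouring APOC1 went with it (3.21 and 3.14 for APOE and APOC1, averaged over glucose).

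All 35 splits of the 8 arrays into 4 and 4 were refitted with limma as a comparison of the 4 and 4 arrays that ignores the other factor. The glucose split called 362 genes, and 2 of the 35 splits gave as many, so the share of splits alone does not exclude chance. The other of these, with the highest other count of 1982, was the split by genotype, which is a structure of the samples and not a random grouping. None of the remaining 33 splits called a gene. The genotype split called 1982 genes and was the 1 split of 35 with as many. The highest other count was 362, from the glucose split. Every other split puts arrays of both lines on each side, so the differences between the lines enter its spread and lower its count. A share of 1 in 35 is also the smallest that these splits can give. The rank of the genotype split therefore cannot exclude chance, and no conclusion is drawn from it.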
